A study of Homo sapiens with 10 samples.

How the data were processed

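Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in CCRF-CEM cells, a line of human T lymphoblasts from a leukemia. Per the labels, the parental cells express SLFN11, a protein recruited to stressed replication forks, and the other line is a knockout of that gene. Each line was given DMSO, 100 nM prexasertib for 2, 4 or 6 h, or 100 nM camptothecin for 4 h. That makes 10 libraries in 10 groups, 1 library per group. Per the series record, the raw reads of the parental 4 h prexasertib library are truncated and could not be replaced by the submitters. Whether its deposited peak list was made from the intact reads is not given in the sources used here, so the number of regions called in all treated libraries is also given without it, and the overlap with camptothecin is also given for the 6 h library.

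One peak list per library was deposited, on build hg19. Per the submitters' processing notes, the tools were Trim Galore 0.6.2, Trimmomatic 0.39, BWA 0.7.17, SAMtools 1.8, Picard 2.9.2 and MACS2 2.1.2. The notes used here give no parameters, and whether reads were shifted for the transposase or duplicates removed is not given in the sources used here. The lists have no header and follow the narrowPeak layout. The deposited score of a peak was the −log10 q-value times 10, rounded down, in at least 99.9885% of the summits of each list. The deposited fold is the enrichment at the summit over the local background of the same library, as the peak caller writes it. The deposited −log10 p-value and −log10 q-value belong to each summit, and the smallest −log10 q in every list was just above 2. The other deposited columns used were the start and end of each peak. No control library is named in the labels.

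Lines with the same start and end are summits of 1 peak and were counted once. Peaks on chromosomes 1 to 22 and X entered the comparisons, and those on other sequences, between 1.75% and 2.64% of each list, were described separately. Peaks of all 10 lists were merged into 35505 regions wherever they overlapped by at least 1 bp. A region was called in a library when a peak of that list lay in it. It was gained when it was called in the treated library and not in the DMSO library of the same genotype, and lost in the opposite case. Width changes were taken from the longest peak of each list in a region, as log2 of treated over DMSO, over regions called in both. Shares have exact (Clopper-Pearson) binomial intervals at 95% confidence, and medians have order-statistic intervals at 95% confidence. These intervals cover counting error over regions only. Regions are not replicates, and with 1 library per group the comparisons rest on no test and no p-value is given for them. Positions are 1-based.

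Depth was not given as a read count. The peak caller's fold is the summit pileup plus 1 over the local background plus 1, and its p-value is a Poisson tail of the same pileup and background. Solving both for a whole pileup gave one that matched the deposited −log10 p within 0.001 for 99.5% to 99.7% of the summits of each list. The smallest background among them is the genome-wide background pileup of the library, which ranged from 1.33 in the parental 4 h prexasertib library to 2.1 in the knockout 2 h prexasertib library and was used as a measure of relative depth. Read counts, fragment lengths and the share of mitochondrial reads, which may enter this background, were not examined. All 10 lists held a peak on the mitochondrial sequence. Summit height is the recovered pileup divided by this background. Heights were compared over the 11546 regions called in all 10 lists with every summit recovered. The fold column was compared between lists only as the height over the local background, which is the highest deposited fold in a region. The 1 added to pileup and background makes that measure depend on depth as well. Recovery and height were added after the data were seen.

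For unequal depth, each library was thinned to a common background pileup, which need not match other properties of the libraries: every pileup was drawn binomially at the ratio of the shallowest background to its own, the background was scaled, and summits under a common −log10 p were dropped. Thinning drops peaks and leaves the width of the others as deposited. The steps were tested on simulated data. Over 43793 simulated summits every pileup was recovered. In a copy of the knockout DMSO list, 200 of 200 added regions, 200 of 200 removed regions and 200 of 200 widened regions were found. Of 60422 simulated unchanged sites at the depths of the knockout 2 h prexasertib and DMSO libraries, 7933 were called gained and 3648 lost before thinning, against 5709 and 6137 after it.

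Overlaps of gained regions that share a DMSO list were set beside the overlap of independent lists. They were also set beside 1000 simulated draws meant to stand for unchanged libraries against that list. The density of accessible regions was taken from the knockout DMSO list, as regions per Mb of chromosome (up to the farthest peak) or as the number of regions within 500 kb to either side.

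Regions were named by a rule fixed before the data were examined. It takes, for each genotype, the 5 regions called in all 10 lists whose smallest log2 width change over the 4 treated libraries is largest. It also takes up to 5 regions called in all 4 treated lists of a genotype and in no other list, by mean −log10 q. Alternatives set before the data were examined were a −log10 q of at least 10, the same number of peaks from every list (15684, the shortest list) and a reciprocal overlap of 50%. The alternatives chosen after the data were seen were thinning, height over the local background, height over regions called in the treated and DMSO lists only, leaving out each list in turn, and a fit with genotype and condition as terms over the 10 libraries, tested by region with t statistics on 4 residual degrees of freedom and a false discovery rate (Benjamini-Hochberg) of 5%. Comparisons at promoters and over fixed gene lists were planned as well and were not run, because no hg19 annotation was used here, and so no region carries a gene name and the SLFN11 locus was not examined. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.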

Results

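The study asks how chromatin accessibility responds to replication stress in leukemia cells with and without SLFN11. Prexasertib inhibits the checkpoint kinase CHK1, and camptothecin traps topoisomerase I on DNA. Accessible regions were called separately in each of the 10 libraries, 1 per genotype and treatment. There are no replicates, so the differences in the comparisons below are between single libraries and were not set against a spread between replicates. The intervals cover counting error over regions only.

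The union of the 10 lists held 35505 regions, of which 11603 (32.7%) were called in all 10 libraries and 9263 (26.1%) in 1 library only. In parental cells 15697 regions were called with DMSO, 15447 after 2 h of prexasertib, 17571 after 4 h, 22834 after 6 h and 21432 after 4 h of camptothecin. In knockout cells the numbers were 19954 with DMSO, 23773, 21166 and 22955 after 2, 4 and 6 h of prexasertib, and 18591 after camptothecin. The median peak width lay between 487 and 520 bp in the parental lists and between 556 and 609 bp in the knockout lists. The genome-wide background pileup, the measure of depth, was 1.63, 1.48, 1.33, 1.52 and 1.45 in the parental libraries in the same order, and 1.59, 2.1, 1.85, 1.99 and 1.74 in the knockout libraries. By this measure each parental treated library was shallower than the parental DMSO library, and each knockout treated library was deeper than the knockout DMSO library.

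**Figure D1:**
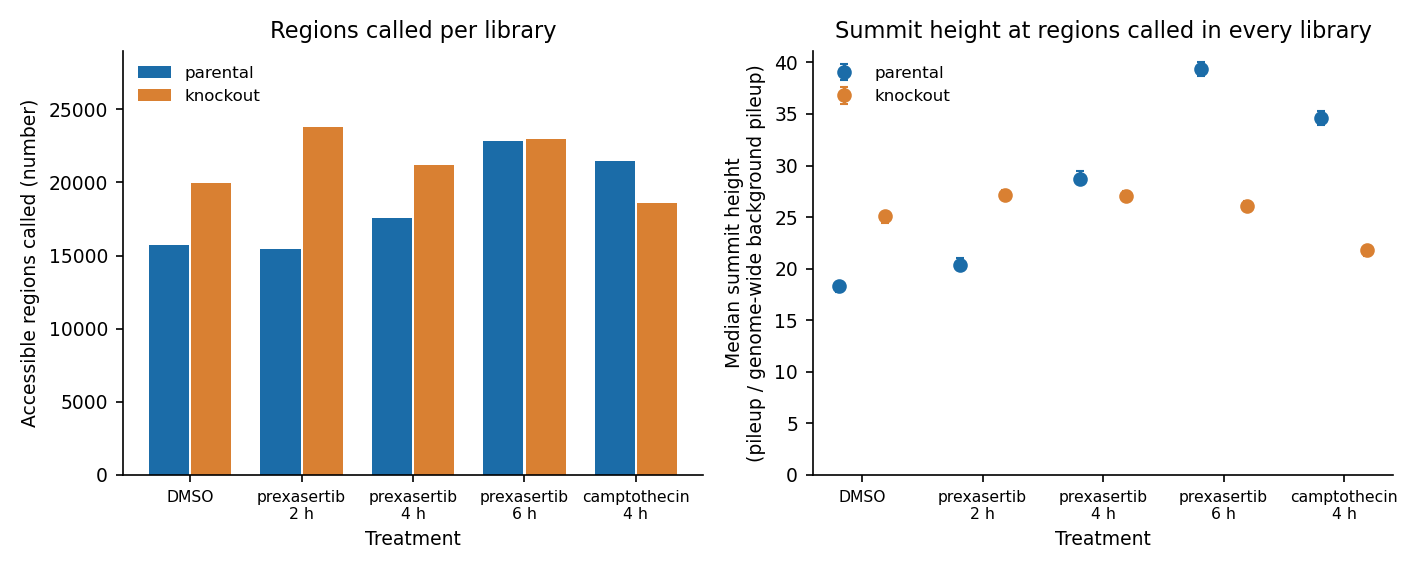
Left, accessible regions called in each library (number, bars from 0) by treatment and genotype. Right, median summit height over the 11546 regions called in all 10 libraries, as pileup over the genome-wide background pileup, with order-statistic 95% intervals over regions. The parental median runs from 18.4 with DMSO to 39.4 after 6 h of prexasertib, while the knockout medians lie between 21.8 and 27.1.

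The first comparison is prexasertib over time against DMSO in parental cells. After 6 h, 8563 regions were gained and 1426 lost, 6.00 gained per region lost, and with a reciprocal overlap of 50% it was 11219 and 3651, or 3.07. After 4 h, 3983 were gained and 2109 lost, and after 2 h, 2536 were gained and 2786 lost. The gained regions made up 37.5% (36.9% to 38.1%) of those called after 6 h, 22.7% (22.1% to 23.3%) after 4 h and 16.4% (15.8% to 17.01%) after 2 h. At 2 h the direction depended on the processing. After thinning to a common background pileup 2569 regions were gained and 2467 lost, and with a −log10 q of at least 10 it was 1339 and 1299. At that stricter threshold the 6 h library had 5700 gained and 352 lost, and the 4 h library 2967 and 593.

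Regions already accessible with DMSO also changed. Over the 11546 regions called in every library, the median summit height after 6 h was 2.07-fold that with DMSO, a log2 change of 1.05 (1.04 to 1.06), and 93.8% of these regions were higher. After 4 h the fold was 1.54 (log2 0.62, 0.62 to 0.64) with 91.9% higher, and after 2 h it was 1.11 (log2 0.15) with 67.6% higher. Before division by the background, and so without correction for depth, the log2 pileup changes were 0 at 2 h (48.5% of regions higher), 0.32 at 4 h and 0.95 at 6 h. The 2 h median height change thus comes wholly from dividing by the lower background of that library. Over the local background in place of the genome-wide one, the log2 changes were 0.04, 0.24 and 0.50 at 2, 4 and 6 h. Peaks at regions shared with DMSO were wider by a median log2 of 0.23 (0.22 to 0.23) after 6 h and 0.09 (0.09 to 0.10) after 4 h. After 2 h the median was 0.00, with an interval from -0.00 to 0.01.

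In knockout cells prexasertib also gave more regions gained than lost, with smaller height changes than in parental cells at 4 and 6 h. After 2 h, 5695 regions were gained and 1876 lost, after 4 h 3913 and 2701, and after 6 h 5246 and 2245. The median log2 height changes were 0.13 (0.12 to 0.13), 0.11 (0.11 to 0.12) and 0.06 (0.06 to 0.07) at 2, 4 and 6 h, with 67.4%, 64.4% and 57.5% of regions higher. They were 0.022, 0.067 and 0.055 over the local background, and 0.092, 0.067 and 0.023 over regions called in the treated and DMSO lists. Before division by the background the pileup changes were 0.52, 0.33 and 0.38. Widths at shared regions changed by a median log2 of 0.18, 0.09 and 0.13. These libraries had 1.32, 1.16 and 1.25 times the background of the knockout DMSO library. After thinning to a common background pileup the gains and losses were 4057 and 2337 at 2 h, 3030 and 2853 at 4 h, and 3713 and 2730 at 6 h.

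**Figure D2:**
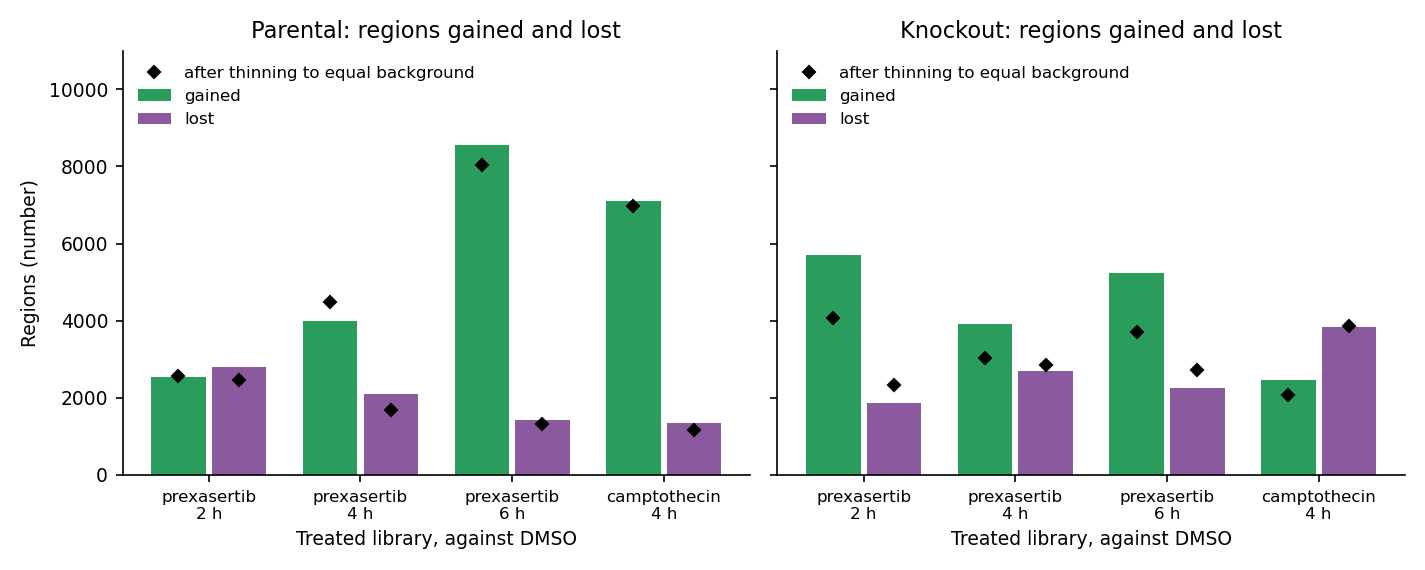
Regions gained (green bars) and lost (purple bars) in each treated library against the DMSO library of the same genotype, in number from 0. Black diamonds give the same counts after every library was thinned to the background pileup of the shallowest. In parental cells 8563 regions were gained and 1426 lost after 6 h of prexasertib, and in knockout cells 2464 were gained and 3827 lost after camptothecin.

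Camptothecin for 4 h gave net changes of opposite sign in the 2 lines. In parental cells 7092 regions were gained and 1357 lost, and in knockout cells 2464 were gained and 3827 lost. The median summit height in parental cells was 1.81-fold that with DMSO (log2 0.85, 0.84 to 0.86), with 95.4% of regions higher. In knockout cells the log2 change was -0.20 (-0.21 to -0.19), and 25.6% of regions were higher. Widths at shared regions changed by a median log2 of 0.22 (0.22 to 0.23) in parental and -0.03 (-0.04 to -0.03) in knockout cells. The height changes over the local background were 0.36 in parental and -0.07 in knockout cells. Before division by the background the log2 pileup changes were 0.68 in parental and -0.074 in knockout cells, with 91.3% and 37.9% of regions higher.

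**Figure D3:**
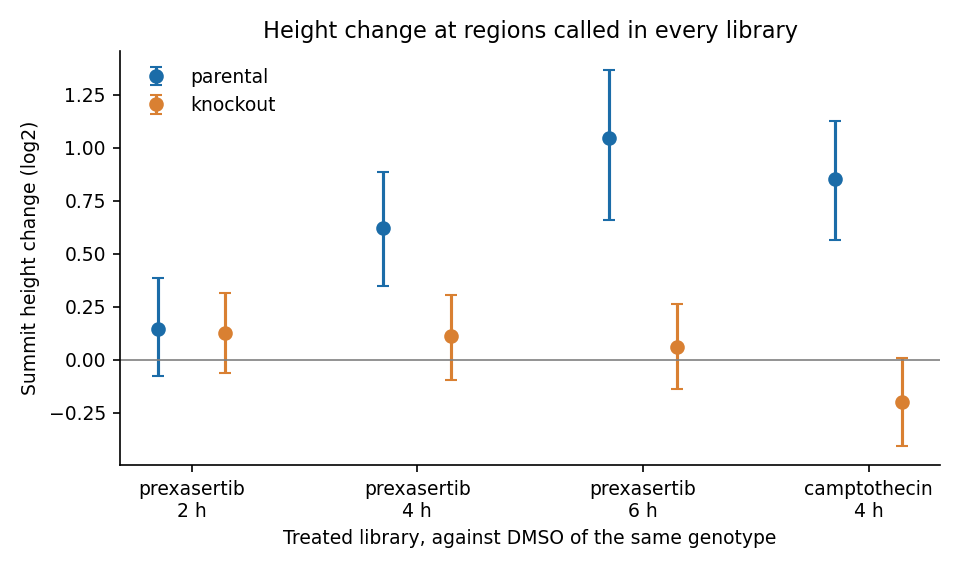
Log2 change of summit height against the DMSO library of the same genotype, over the 11546 regions called in all 10 libraries. Points are medians and bars run from the lower to the upper quartile of the regions. The parental medians are 0.15, 0.62 and 1.05 for prexasertib and 0.85 for camptothecin, and the knockout medians are 0.13, 0.11, 0.06 and -0.20.

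Parental and knockout cells were then compared at the same condition. With DMSO, 1466 regions were called in parental cells only and 5723 in knockout cells only, and the parental summits were lower, with a median log2 ratio of -0.42 (-0.43 to -0.41). After 2 h of prexasertib 863 were parental only and 9189 knockout only, at a log2 height ratio of -0.38. After 4 h the numbers were 1786 and 5381 at 0.10, and after 6 h 4670 and 4791 at 0.55. At 6 h the order of the counts depended on the processing, with 4971 parental only and 3202 knockout only after thinning, and 2110 and 1534 with a −log10 q of at least 10. After camptothecin 5396 were parental only and 2555 knockout only, at 0.64. The log2 width ratios of parental over knockout, in the same order from DMSO to camptothecin, were -0.21, -0.40, -0.21, -0.11 and 0.05.

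The height change on treatment was larger in parental than in knockout cells by a median log2 of 0.03 (0.02 to 0.04) at 2 h, 0.51 (0.50 to 0.52) at 4 h and 0.97 (0.96 to 0.98) at 6 h of prexasertib. The differences over the local background were 0.007 (-0.002 to 0.016), 0.17 and 0.45. Before division by the background, and so without correction for depth, they were -0.51, -0.008 (-0.019 to 0.001) and 0.55. A larger parental change thus appeared at 4 h only over a background, and at 2 h only over the genome-wide one. The parental 4 h library, with the lowest background of all, is the one whose raw reads are truncated. With camptothecin the difference was 1.06, against 0.42 over the local background and 0.75 before division. The difference between genotypes has no replicate check. Of the 19808 regions not called with DMSO in parental cells, 5723 (28.9%) were called in the knockout DMSO library. Of the 8563 gained after 6 h, 3309 (38.6%) were called there, and 2650 were called in none of the 5 knockout libraries. For the 3983 gained after 4 h these numbers were 2214 (55.6%) and 582. Among regions called in neither DMSO library, 1600 were gained in both genotypes after 6 h, where independent lists would share 1679. The numbers were 499 against 377 after 2 h, 665 against 406 after 4 h and 691 against 557 after camptothecin. Each of these regions entered because at least 1 treated library called it, which raises the independent values. The 6 h number thus cannot be read as sharing at or below that of unrelated lists.

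Prexasertib and camptothecin were compared at 4 h, the time they share. In parental cells 2661 of the 3983 regions gained with prexasertib were also gained with camptothecin, 66.8% (65.3% to 68.3%). Independent lists would share 1426, and the draws simulated for a shared DMSO list gave 63.6% on average and 65.8% at most. For regions gained in the parental 6 h library the share was 49.6% (48.6% to 50.7%), below the simulated average of 54.0%, and independent lists would share 35.8%. In knockout cells 1037 of 3913 were shared, 26.5% (25.1% to 27.9%), against 620 for independent lists and 38.6% in the simulation. The parental 6 h share and the knockout share thus fell below the simulated averages. The simulation is therefore no firm baseline, and no conclusion is drawn from the parental 4 h share lying above it. There was only 1 DMSO library per genotype, so part of the excess over independent lists may come from the shared control. With equal list lengths the shares were 54.2% in parental and 40.6% in knockout cells. Summits in parental cells were lower with prexasertib than with camptothecin by a median log2 ratio of -0.23 (-0.23 to -0.22), and in knockout cells they were higher, at 0.31 (0.31 to 0.32).

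The height changes of both drugs were also related region by region. In parental cells the covariance of the 4 h prexasertib and 4 h camptothecin log2 changes was 0.141, and the shared DMSO library alone gave 0.0840 in simulation. In knockout cells the observed covariance was 0.0492, below the simulated 0.0632, so the simulation may overstate the part of the shared library and is no firm baseline. A comparison that shares no library, the 6 h prexasertib change from DMSO against the change from 2 h of prexasertib to camptothecin, gave a correlation across regions of 0.458 in parental and 0.000829 in knockout cells. Regions are not independent replicates.

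The parental height change was uneven along the genome. After 6 h of prexasertib the median log2 change was 1.39 on chromosome 19, 1.34 on chromosome 17, 1.33 on chromosome 22 and 1.25 on chromosome 16. It was 0.73 on chromosome 4, 0.83 on chromosome 18 and 0.84 on chromosome X. After camptothecin the medians ran from 0.67 on chromosome 4 to 1.07 on chromosome 22. In knockout cells they ran from -0.00 to 0.11 after 6 h of prexasertib and from -0.25 to -0.14 after camptothecin. Over the local background the parental medians after 6 h of prexasertib ran only from 0.38 on chromosome 4 to 0.64 on chromosome 22.

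**Figure D4:**
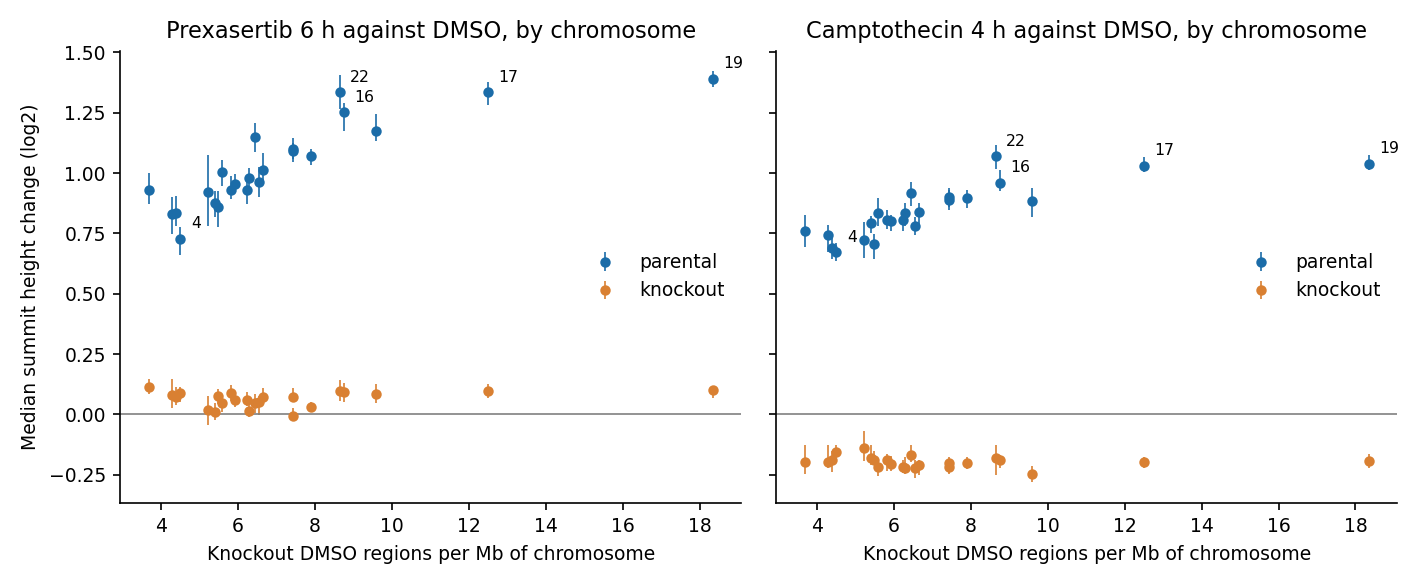
Median log2 summit height change of each of the 23 chromosomes (1 to 22 and X) against the density of accessible regions in the knockout DMSO library, in regions per Mb, for 6 h of prexasertib and 4 h of camptothecin. Bars are order-statistic 95% intervals over regions. Parental medians after prexasertib run from 0.73 on chromosome 4 to 1.39 on chromosome 19, and knockout medians stay between -0.00 and 0.11.

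Individual regions were named by the fixed rule. They are given by hg19 position without annotation. In parental cells the smallest log2 width change over the 4 treated libraries was largest at chromosome 17, 65373068 to 65375113, where the longest peak measured 223 bp with DMSO, 1361, 1802 and 2046 bp after 2, 4 and 6 h of prexasertib, and 1744 bp after camptothecin. In untreated knockout cells this region already measured 1741 bp. Its parental summit height was 14.2 at 2 h against 15.3 with DMSO, so the peak was wider there without a higher summit. The region at chromosome 19, 50320710 to 50322118, went from 253 bp with DMSO to between 998 and 1409 bp in the 4 treated parental libraries. It measured 421 bp in untreated knockout cells. The others by this rule were at chromosome 19, 52800035 to 52800949 and 6516101 to 6517208, and at chromosome 9, 139581187 to 139582316. Their widths with DMSO were 204, 273 and 256 bp, and in no treated parental library were they below 713, 870 and 807 bp. In untreated knockout cells they measured 847, 909 and 677 bp. At the chromosome 9 region the parental summit height was 15.3 with DMSO and 14.9 at 2 h, while it rose at 2 h at the chromosome 19 regions.

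In knockout cells the same rule gave chromosome 6, 27791586 to 27792779, at 204 bp with DMSO and 813, 1004 and 682 bp after 2, 4 and 6 h of prexasertib. It also gave chromosome 1, 26185376 to 26186291, chromosome 14, 106465317 to 106466468, chromosome 3, 158526467 to 158527737, and chromosome 7, 150054478 to 150055314. At the chromosome 6 region the parental DMSO peak measured 887 bp. A short DMSO peak sets all 4 width changes of a genotype in this rule at once.

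Only 3 regions were called in all 4 parental treated libraries and in no other library. They lay at chromosome 2, 12426459 to 12426903, chromosome 7, 145833585 to 145833969, and chromosome 10, 94661517 to 94662002, with mean −log10 q in those libraries of 7.93, 7.88 and 6.12. Leaving the 4 h prexasertib list out of the condition gave 22 regions and leaving the 2 h list out gave 67. The regions called with both 6 h prexasertib and camptothecin in parental cells, and neither with DMSO nor in knockout cells, numbered 428. In knockout cells 58 regions were called in all 4 treated libraries only, which became 119, 186 and 193 without the 4 h prexasertib, DMSO and camptothecin lists, and 205 in the 6 h prexasertib and camptothecin libraries with none in DMSO or parental cells. The strongest of the 58 was at chromosome 2, 243152480 to 243152824, with a mean −log10 q of 25.3. The next were at chromosome 16, 78344706 to 78345484 (11.4), chromosome 10, 30348256 to 30348622 (9.28), chromosome 8, 133997535 to 133998079 (9.04), and chromosome 15, 45900536 to 45900920 (8.50).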

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

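The tests of depth, of the parental DMSO library, of a single enrichment factor and of the genotype were chosen after the results were seen; the 6 h test and the test of weak peaks on the chromosome 6 haplotype sequences were set before their values were computed, and the same test in the other libraries and its intervals were added after. Camptothecin gave changes of opposite sign in the 2 genotypes: a median log2 height change of 0.85 in parental and -0.20 in knockout cells, a median log2 width change of 0.22 and -0.033, and 5735 more regions gained than lost against -1363. After 2 h of prexasertib regions gained minus lost was -250 in parental and 3819 in knockout cells, and after thinning to a common background pileup it was 102 and 1720. With 1 library per group these differences between genotypes were not tested.

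The treated parental libraries had higher summits over the background and, after 4 h or more, more regions than the parental DMSO library. For the numbers of regions, lower depth argues against depth as the source, as far as the background pileup measures depth. After thinning, the 6 h library had at least 6.01 regions gained per region lost in each of 20 draws, against 6.00 before. Thinning takes more from the DMSO library, whose background is higher. It was thus not set up to lower this ratio and adds little to that argument. For the heights, lower depth is no such argument by itself, since dividing by a lower background raises them. Before division the log2 pileup changes were 0, 0.32 and 0.95 at 2, 4 and 6 h of prexasertib and 0.68 with camptothecin. At 2 h depth is thus not argued against as the source of the higher summits. A low parental DMSO library alone is argued against by the log2 height change of 0.88 (0.87 to 0.89) from the parental 2 h to the 6 h library, which does not use it. One enrichment factor for the whole library is argued against by the spread of 0.66 between the medians of the chromosomes at 6 h. It lay above the highest value of 0.28 in 1000 reassignments of regions at equal height in the knockout DMSO library. Over the local background the spread was 0.26 against 0.18. The parental DMSO height was not matched in these reassignments. A response that differs with the SLFN11 genotype, for which parental minus knockout was 0.97 at 6 h and 0.45 over the local background, and a difference in library quality that acts unevenly along the genome cannot be told apart with 1 library per group, and the number of knockout clones is not given in the sources used here.

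Peaks on the haplotype sequences of chromosome 6, alternative copies of the MHC that the comparisons left out, rose in number above the upper counting limit of the DMSO library in the treated libraries except knockout camptothecin. Parental cells had 73 with DMSO (upper limit 91.8), 94, 187 and 316 after 2, 4 and 6 h of prexasertib and 282 after camptothecin, and knockout cells had 128 (upper limit 152), 216, 210, 226 and 119. Parental peaks in the MHC on chromosome 6 itself numbered 7 (upper limit 14.4), 13, 23, 47 and 33, and on the rest of chromosome 6 813, 828, 878, 1117 and 1102. The limits on the haplotype sequences take peaks on copies of the same loci as separate and leave out the error of the treated count. They are thus too narrow, and the parental rise at 2 h, close to its limit, is not established. A rise specific to the MHC had a bound of 0.3 for the median log2 height change above that of the rest of chromosome 6, and the parental values lay under it, at 0.070, 0.041 and 0.28 after 2, 4 and 6 h and 0.23 with camptothecin. Their intervals over regions ran from -0.087 to 0.28, -0.098 to 0.22, 0.12 to 0.42 and 0.03 to 0.35. But the 7 sequences are copies of the same loci. With the regions of 1 copy all 4 intervals include 0.3 and also include no difference, so this stays open. The peak counts rose more in the MHC than on the rest, but they cannot decide it, since weak peaks crossing the calling threshold could raise them too. Weak peaks crossing that threshold go with the parental DMSO list. There 54.8% (42.7% to 66.5%) of the haplotype peaks had a −log10 q under 5, against 22.9% (20.0% to 25.9%) on the rest of chromosome 6. In the knockout DMSO list the intervals of 30.5% (22.6% to 39.2%) and 21.3% (18.8% to 24.0%) overlap, which does not show equal shares. In the knockout treated lists the shares were 35.6% to 47.1% against 21.6% to 25.4%. In the parental treated lists the haplotype share was the higher too, but at 6 h only by 25.0% against 24.5%.

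On an unplaced contig that carries ribosomal DNA, parental cells had 14 peaks with DMSO (upper limit 23.5). They had 14, 21 and 26 after 2, 4 and 6 h of prexasertib and 24 after camptothecin, and knockout cells had between 14 and 19.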

How the results depend on the processing

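Thinning, the local background, the pairwise choice of regions, the height results under every setting and the lists left out in turn were chosen after seeing the data; the other alternatives were planned. Values follow the order 2, 4 and 6 h of prexasertib and 4 h of camptothecin. The labels give no replicate numbers, so no libraries pair by replicate. The genotypes can be set side by side by condition, and a fit of the log2 heights with genotype and condition as terms, added after seeing the data, called 0 of 11546 regions at a false discovery rate of 5% for the genotype or any treatment, on 4 residual degrees of freedom. It takes the differences between genotypes in their response for error, at a median residual SD of 0.41, so it does not test them. The alternatives at promoters and over gene lists were not run, because they need an hg19 annotation. None of the 16 genome-wide median width and height changes changed its sign under an alternative run here. The height medians after thinning follow the main ones by construction and add nothing to this. Over the local background some height medians of single chromosomes did, at 2 h of prexasertib on parental chromosomes 10 (0.15 to -0.00061) and 21 (0.081 to -0.0015) and knockout chromosome 18 (0.15 to -0.0084), and at 6 h on knockout chromosome 11 (-0.0044 to 0.058). After 4 and 6 h of prexasertib and after camptothecin, parental cells gained more regions than they lost under the stricter threshold, reciprocal overlap and thinning. Thinning was not set up to lower the parental net gains, since the DMSO library had the highest background of that line. The equal list length fixes gains and losses to near equality by construction.

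With a −log10 q of at least 10, fewer peaks enter and there were 1339, 2967, 5700 and 4696 gained and 1299, 593, 352 and 312 lost in parental cells, and 3331, 2080, 2565 and 985 gained and 502, 818, 723 and 1898 lost in knockout cells. The log2 width changes were 0.0050, 0.086, 0.20 and 0.19 in parental cells, and 0.14, 0.082, 0.12 and -0.020 in knockout cells, and the log2 height changes 0.18, 0.65, 1.11 and 0.87 in parental cells, and 0.13, 0.14, 0.079 and -0.19 in knockout cells. In the order from DMSO to camptothecin, regions called in one genotype numbered 512, 141, 703, 2110 and 3108 in parental cells only, and 3442, 5860, 2521, 1534 and 741 in knockout cells only. The share of regions gained at 4 h of prexasertib that camptothecin also gained was 87.1% in parental and 29% in knockout cells.

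With equal list lengths there were 2635, 2626, 3050 and 2739 gained and 2662, 2677, 3061 and 2734 lost in parental cells, and 2082, 2097, 2142 and 2219 gained and 2012, 2075, 2104 and 2246 lost in knockout cells. The log2 width changes were 0.0025, 0.10, 0.25 and 0.24 in parental cells, and 0.16, 0.086, 0.13 and -0.031 in knockout cells, and the log2 height changes 0.15, 0.66, 1.1 and 0.89 in parental cells, and 0.13, 0.12, 0.067 and -0.20 in knockout cells. Regions called in one genotype numbered 2600, 2500, 2160, 2272 and 2469 in parental cells only, and 2708, 2705, 2341, 2429 and 2545 in knockout cells only. The shared gains were 54.2% in parental and 40.6% in knockout cells.

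With reciprocal overlap of 50% fewer peaks match, and there were 4104, 5921, 11219 and 9638 gained and 4341, 3847, 3651 and 3562 lost in parental cells, and 7911, 5829, 7328 and 4268 gained and 4182, 4608, 4335 and 5639 lost in knockout cells. The log2 width changes were 0.0048, 0.087, 0.20 and 0.19 in parental cells, and 0.15, 0.079, 0.11 and -0.028 in knockout cells. Regions called in one genotype numbered 3610, 4006, 4543, 7955 and 7986 in parental cells only, and 7911, 12273, 7991, 7681 and 4840 in knockout cells only. The shared gains were 47.4% in parental and 19.5% in knockout cells.

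After thinning to the background of the shallowest library, which left 5709 gained and 6137 lost among simulated unchanged sites, there were 2569, 4494, 8040 and 6971 gained and 2467, 1691, 1313 and 1155 lost in parental cells, and 4057, 3030, 3713 and 2082 gained and 2337, 2853, 2730 and 3871 lost in knockout cells. The net gain of the knockout prexasertib libraries thus fell from 3819, 1212 and 3001 regions to 1720, 177 and 983. Over 20 draws gained per lost lay between 1.69 and 1.77, 1.04 and 1.09, and 1.32 and 1.38. In parental cells the net change at 2 h went from -250 to 102. Regions called in one genotype numbered 1413, 1145, 2415, 4971 and 5592 in parental cells only, and 5388, 6738, 3764, 3202 and 1962 in knockout cells only. The shared gains were 66.7% in parental and 28.1% in knockout cells, and the log2 height changes 0.15, 0.62, 1.04 and 0.85 in parental cells, and 0.13, 0.11, 0.059 and -0.20 in knockout cells. Thinning does not test the heights, since pileup and background shrink by the same ratio and the same regions are compared. It does not test the widths either, since it leaves the width of the peaks that stay. The depth limits the width changes, which in knockout cells came with deeper treated libraries.

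Over the local background the log2 height changes were 0.035, 0.24, 0.50 and 0.36 in parental cells, and 0.022, 0.067, 0.055 and -0.066 in knockout cells. That background holds the reads of the peak's own surroundings; the cause of the smaller changes was not tested. Over regions called in the treated and DMSO lists they were 0.15, 0.59, 0.96 and 0.79 in parental cells, and 0.092, 0.067, 0.023 and -0.20 in knockout cells. The 3 regions called in the 4 parental treated libraries only became between 4 and 67 when 1 of the 10 lists was left out, with 22 without the parental 4 h list and 67 without the parental 2 h list. The 58 of the knockout became between 65 and 193, with 186 without the knockout DMSO list and 193 without the knockout camptothecin list. The cause was not tested for the other changes.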

Other observations

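The test of density at equal baseline height was chosen after the unequal change between chromosomes was seen, as were the values that follow. In parental cells the height change followed how densely accessible regions lie along the genome. Over the 23 chromosomes, the number of regions per Mb in the knockout DMSO library and the median log2 height change after 6 h of prexasertib had a Spearman's rho of 0.93 and a Pearson's r of 0.84, and r was 0.86 without chromosomes 19 and 17. The rho was 0.79 at 2 h, 0.94 at 4 h and 0.88 with camptothecin. At 2 h many chromosomes had the same median of 0.145, which is the offset from dividing by the background, so that rho rests on the others. In knockout cells the rho values were -0.31, 0.45, 0.17 and -0.32, at equal baseline height -0.11, 0.52, 0.27 and -0.21, and over the local background -0.02, -0.45, 0.21 and -0.48, so at 4 h the sign depended on the background. Chromosomes of one library are not replicates, so no p-value is given.

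The same held on a finer scale. Regions with at most 7 neighbours within 500 kb to either side had a median log2 height change of 0.76 (0.73 to 0.78) in the parental 6 h library, and regions with 22 or more had 1.31 (1.29 to 1.32), with 0.96, 1.06 and 1.19 in between. With camptothecin these ends were 0.67 and 1.02. In the knockout 6 h library they were 0.05 and 0.08, and with knockout camptothecin -0.18 and -0.22. Over the local background the parental 6 h ends were 0.40 and 0.60.

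A hypothesis is that in the parental cells summits rise more where accessible regions lie denser. At equal baseline height, measured in the knockout DMSO library, the rho over chromosomes at 6 h was 0.91, so a difference in that height alone does not account for it. The parental DMSO height, which enters the change itself, was not matched. Over the local background the rho was 0.86 at 6 h and 0.21 at 2 h. GC content or fragment length bias may give the same picture and cannot be told apart from it, since the rho of 0.93 serves either explanation and base content was not measured. Gene density was not measured, and with 1 library per group a dependence on SLFN11 was not tested.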
